A study of Mus musculus with 8 samples.

How the data were processed

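Gene expression was measured by RNA sequencing of whole tissue in 8 mouse libraries, 3 of wild-type small intestine and 5 of small intestinal adenoma. Per the labels' protocols, RNA was extracted with Qiagen RNeasy kits, libraries were made with the TruSeq RNA v2 kit, which does not keep strand, and read on an Illumina NextSeq as paired ends of 36 cycles each. Per the labels, the mice were on an inbred C57BL/6J background. The names of the sequencing runs in the labels show the same lane for all 8 libraries, so no batch was given that could be tested. The authors deposited a table of raw counts per gene. Per the submitters' processing notes, FastQC, TopHat2 and HTSeq were used with genome build GRCm38. Their versions, the annotation release, the strand setting and any filter are not given in the sources used here. Short paired ends and a counter that leaves out reads of more than 1 gene lower the counts of genes with near-identical copies, such as defensins and haemoglobins. With an unstranded kit, reads of overlapping antisense genes cannot be told apart.

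The table held 39179 genes under Ensembl identifiers, of which 10415 had 0 counts in all libraries. Symbols were found for 37607 identifiers, and the 1572 without one took 0.30% to 0.41% of the counts. All 8 columns of values were assigned to a library by name. Gene positions were taken from GENCODE release M21, which is also on GRCm38. Total counts were 18040301 to 28343915 per library. Mitochondrial genes took 1.82% to 2.79% of the counts. The genes Gm42418, Lars2, Gm15564 and Gm26917, which collect ribosomal RNA reads, took 10.7% to 23.5%. No pair of libraries of a group agreed within sampling noise, since the chi-square per degree of freedom over genes with at least 20 counts ran from 20.1 to 149, so each library counted as 1 replicate.

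The counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which kept 18345, libraries were scaled by TMM, and adenoma was tested against wild type with robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. Sizes were tested against a log2 fold change of 1 with glmTreat. CPM values are counts scaled by the TMM library sizes, log2 CPM values use a prior count of 2, and the SE of a log2 fold change is its size divided by the square root of the F statistic. The common biological coefficient of variation was 0.28. Where a gene had 0 counts in wild type, a floor of 3 counts over that group gave a lower bound, and with 1 to 3 counts the ratio of summed counts has an exact 95% interval. Intervals and floors cover counting error only. Counts were simulated for this comparison with the real means, library sizes and dispersions of 18345 genes. Changed genes were drawn only from genes above a minimum mean count, so the shares recovered do not cover genes with low counts. Of genes changed by a factor of 2, 40% were recovered, and 85% of those changed by a factor of 4, with 7.53% of the calls false. Few genes were changed, and 146 were called against 10657 in the real fit. Adjustment is stricter with few calls, so these shares do not give what the real fit recovers.

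The 34 gene lists held 452 genes, of which 430 were tested. The erythrocyte gene Ahsp was absent from the table and was not analysed here. Lists with at least 3 tested members entered camera of limma 3.58.1 with a preset correlation between genes of 0.01. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance and not whether they differ from other genes, were alternatives. Genes to be named were fixed by rule before the data were examined. They were Apc and Notum, the 10 largest changes each way among called genes with a mean of at least 5 CPM and separate groups, up to 4 members of each list with the smallest adjusted p plus the leading member of the minority direction or, where none passed, the 2 with the highest mean, and the 8 genes with the largest SD of log2 CPM over the adenomas. Gene models named by number alone, identifiers without a symbol and immunoglobulin or T cell receptor segments were passed over, and families with near-identical copies gave at most 2 members to the largest changes. The text names part of the genes the rule takes, and some of the others are not reported here. Other genes are named with the statement that they were chosen after their values were seen.

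The alternatives fixed in advance were RLE, upper-quartile and total-count scaling, scaling to equal summed counts of pan-epithelial genes, no filter and a filter of 5 CPM in at least 3 libraries, a block for the replicate number, leaving out each library, DESeq2 1.42.0 and limma-voom. Those added after seeing the data were leaving out wild type 1 and adenoma 5 together, leaving out the 4 ribosomal RNA genes before library sizes were taken, and the sex pattern as a covariate. All 56 splits of the 8 libraries into groups of 3 and 5 were refitted. No reads were aligned or counted anew.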

Results

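RNA was sequenced from 8 mouse intestinal samples. The 3 wild-type samples were small intestine of mice carrying VilCreER, a tamoxifen-activated Cre recombinase driven by the villin promoter in intestinal epithelium. The 5 adenoma samples were labelled as small intestinal adenomas, which are benign epithelial tumours, from VilCreER mice with 1 floxed and 1 normal allele of Apc. Apc encodes a scaffold of the complex that marks beta-catenin for degradation, and it restrains Wnt signalling. The comparison asks how gene expression in adenomas arising after Apc loss differs from that of small intestine. Total counts per library ran from 18040301 to 28343915, and 16985 to 17965 genes had at least 10 counts in a library. Values are given in CPM, counts scaled to library size, as mean ± SD with n = 3 for wild type and n = 5 for adenoma, and log2 fold changes as adenoma over wild type ± SE. The labels do not say whether the libraries came from separate mice, so p-values measure only the spread between these samples.

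The libraries differed in ways other than their group. Xist, which is transcribed from the inactive X chromosome, stood at 1.56 to 1.75 CPM in the wild-type libraries and at 1.17 CPM in adenoma 1, against 432 to 761 CPM in adenomas 2, 3, 4 and 5. The Y-linked gene Ddx3y ran the other way, at 70.6 to 77.5 CPM in wild type, 75.6 CPM in adenoma 1 and at most 0.0939 CPM in the other adenomas. Adenoma 2 stood apart from the other adenomas on the second principal component. It held 245.5 CPM of Hoxb13, a homeobox gene of the hindgut, against at most 0.894 CPM in any other library. Gata4, a transcription factor of the upper small intestine, was at 0.470 CPM in adenoma 2 and at 68.4 to 84.4 CPM in the other adenomas. Both genes were picked after their values were seen. Pancreatic RNA was present in wild type 1 and adenoma 5, where the pancreatic lipase gene Pnlip, also picked afterwards, was at 190.04 and 63.5 CPM against at most 0.798 CPM elsewhere. A group of 4 genes that overlap ribosomal RNA repeats or attract its reads took 10.7% to 23.5% of the counts, with the highest shares in wild type 2 and adenoma 2.

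**Figure D1:**
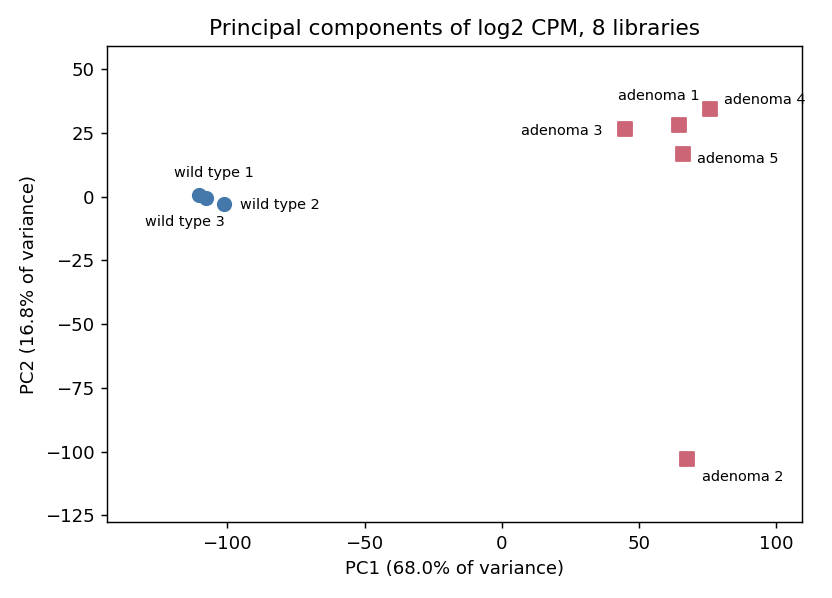
Each point is 1 library placed by the first and second principal components of log2 CPM (arbitrary units), with circles for wild type and squares for adenoma. The first component, with 68.0% of the variance, separates the groups, and the second, with 16.8%, separates adenoma 2 from the rest.

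In the main fit, adenomas and wild-type intestine differed in most of the genes tested. With any 1 wild-type library left out, the genes called were no longer the majority. Of 18345 genes tested, 5558 were higher and 5099 lower in adenoma (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), so that 52.2% of the calls were higher. A test against a factor of 2 called 2417 genes, 1038 higher and 1379 lower. The 2 groups did not overlap for 10430 genes, or 56.9% of those tested, where chance alone gives 3.57%. The higher and lower split rested on scaling by the bulk of genes. With libraries scaled to equal summed counts of pan-epithelial genes, the median log2 fold change of all genes moved from 0.04 to -0.50, with 1343 genes higher and 7343 lower, or 15.5% of calls higher. With the male or female pattern of Xist and Y genes as a covariate, chosen after seeing the data, 3074 genes were higher, 2298 lower and 855 changed by more than a factor of 2. No wild-type library had the female pattern, so the group difference of that fit rests on adenoma 1 alone, and a call lost there says nothing about sex as a cause.

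Gene lists fixed before the data were examined were tested with camera. With a preset correlation between genes, 12 of the 34 lists were called higher and 5 lower. With the correlation estimated from the data, 3 were called higher and 0 lower, namely Wnt and beta-catenin targets, secreted Wnt antagonists and fetal-like genes. The preset test also called lists in each of the 55 other groupings of the 8 libraries into 3 and 5. Each of these mixes wild type and adenoma, so part of the group difference can remain in them. Unless a figure is given, the counts of members adjusted over the list alone equalled those over all genes.

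The floxed gene itself was read first. Apc (ENSMUSG00000005871, GRCm38 chromosome 18, 34220924 to 34322552, plus strand) stood at 199 ± 10.8 CPM in wild type and 146 ± 11.4 CPM in adenoma, a log2 fold change of -0.45 ± 0.09 (adjusted p = 0.00374). Each adenoma, at 132 to 159 CPM, lay below each wild-type library, at 191 to 211 CPM. The counts cover the whole gene and the labels do not give the floxed part, so they do not measure recombination. The call was lost with the sex pattern as a covariate, where the log2 fold change was -0.41 (adjusted p = 0.0987).

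Targets of Wnt signalling rose as a group. All 20 Wnt and beta-catenin targets were called higher, with a median log2 fold change of 1.97 (adjusted p = 9.74e-14; adjusted p = 0.0428 with an estimated correlation). Notum (ENSMUSG00000042988, chromosome 11, 120653788 to 120661175, minus strand), a secreted enzyme that inactivates Wnt proteins by removing their lipid, rose from 0.587 ± 0.114 to 223 ± 44.1 CPM, a log2 fold change of 8.55 ± 0.28 (adjusted p = 1.55e-06). Nkd1, a feedback inhibitor of Wnt signalling, rose from 7.25 ± 0.411 to 196 ± 19.0 CPM. Prox1, a transcription factor induced by beta-catenin in intestinal tumours, rose from 3.75 ± 1.01 to 126 ± 21.4 CPM, and the crypt receptor gene Ephb3 from 18.1 ± 3.19 to 132 ± 26.3 CPM.

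Secreted Wnt antagonists moved with the targets. Of 9 tested, 8 were higher and 1 lower, with a median log2 fold change of 2.40 (adjusted p = 4.84e-06; adjusted p = 0.0428 with an estimated correlation). Wif1, which binds Wnt proteins outside the cell, rose by 7.77 ± 0.40 on the log2 scale (adjusted p = 8.55e-06) to 138 ± 43.0 CPM. Dkk3 rose by 2.08 ± 0.12 to 155 ± 16.6 CPM and Sfrp2 by 3.17 ± 0.41 to 3.61 ± 1.32 CPM. Sfrp5 was the lower member, at 1.73 ± 0.670 CPM in wild type and 0.501 ± 0.469 CPM in adenoma, and its call (adjusted p = 0.0320) was lost when any 1 of wild type 1, wild type 3 and adenomas 1, 3 and 4 was left out, with an adjusted p of up to 0.132. Notum belongs to both lists. Wnt ligands and R-spondins went both ways, with 5 of 10 higher and 2 lower (adjusted p = 0.179). Wnt5a rose from 16.6 ± 1.90 to 66.0 ± 6.63 CPM, Wnt6 from 1.12 ± 0.252 to 14.3 ± 8.39 CPM and Wnt11 from 0.320 ± 0.0954 to 3.87 ± 1.71 CPM, while Wnt4 fell from 11.6 ± 1.45 to 3.00 ± 2.03 CPM.

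**Figure D2:**
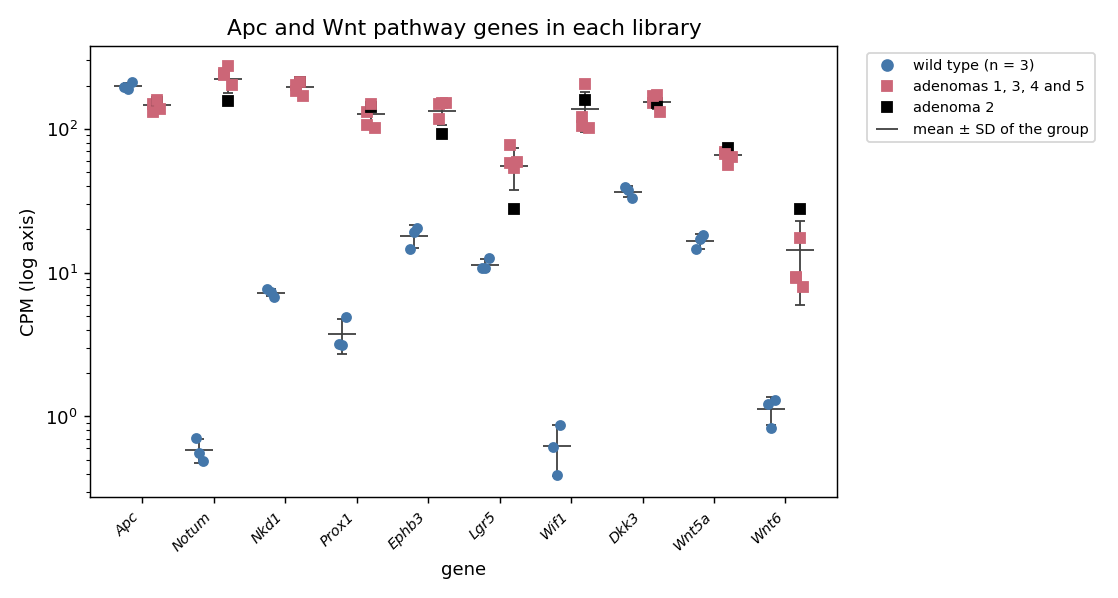
CPM of Apc and 9 genes of the Wnt pathway on a log axis, with 1 point per library and bars for the group mean ± SD (n = 3 wild type, n = 5 adenoma). Notum lies between 157 and 272 CPM in the adenomas and at up to 0.713 CPM in wild type, and Apc is the gene of this set that is lower in adenoma.

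The 10 largest increases among genes at 5 CPM or more with separate groups included secreted and stomach-type proteins. Sox21, a transcription factor, had 0 counts in wild type and 18.3 ± 8.15 CPM in adenoma, at least 341-fold higher against a floor of 3 counts over the wild-type group. T, which encodes the mesodermal transcription factor brachyury, had 1 count in wild type and 24.1 ± 11.3 CPM in adenoma, a ratio of 1392 with a 95% counting interval of 249.6 to 54980.2. Wfdc18 rose by 9.08 ± 0.72 on the log2 scale (adjusted p = 4.92e-05) to 303 ± 148 CPM, and Chit1, a chitinase, had 1 wild-type count and 11.2 ± 7.65 CPM in adenoma. The gastric surface genes Gkn1 and Tff1 reached 46.9 ± 34.7 and 17.5 ± 19.5 CPM from 3 and 2 wild-type counts. Bpifb1 and Bpifb5, of a family of secreted lipid-binding proteins, reached 29.3 ± 22.2 and 59.5 ± 33.1 CPM. In adenoma 2 these 4 genes were far lower, at 0.751, 0.470, 0.329 and 2.77 CPM. Krt36, with 44.9 CPM in adenoma 2 and at most 1.99 CPM in the other adenomas, and Mug1, with 37.9 CPM in adenoma 4 and at most 4.10 CPM in the others, lost their calls when any wild-type library was left out, with adjusted p of up to 0.107 and 0.0983. The limma-voom test did not call Bpifb1, Gkn1, Tff1, Krt36, Bpifb5 or Mug1, at adjusted p from 0.0958 to 0.269.

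The 10 largest decreases included transporters and brush border enzymes. Slc5a12, a lactate and monocarboxylate transporter, fell from 353 ± 61.4 to 2.69 ± 3.26 CPM, a log2 fold change of -7.05 ± 1.10 (adjusted p = 0.00121). Enpp7, the intestinal alkaline sphingomyelinase, fell from 328 ± 81.2 to 5.25 ± 6.93 CPM. Anpep, an aminopeptidase of the brush border, fell from 2529 ± 593 to 75.1 ± 73.0 CPM, and Naaladl1, another peptidase, from 418 ± 32.9 to 16.03 ± 20.9 CPM. Cubn, the receptor for vitamin B12 bound to intrinsic factor, fell from 886 ± 599.9 to 26.5 ± 29.3 CPM. Mbl2, a secreted lectin, fell from 49.1 ± 19.5 to 0.473 ± 0.458 CPM and Ano3 from 20.2 ± 7.74 to 0.139 ± 0.118 CPM, a log2 fold change of -7.15 ± 0.47. Slc5a4a, Unc93a2 and Slc13a2os made up the rest, with log2 fold changes of -5.12, -5.01 and -5.50. Slc13a2os is antisense to another gene and the counting's strand setting is not given, so its reads cannot be assigned to 1 strand. With the sex pattern as a covariate, where adenoma 1 alone is set against wild type, the calls of Slc5a12, Enpp7, Slc5a4a, Anpep, Unc93a2 and Naaladl1 were lost at adjusted p from 0.0517 to 0.185, while their log2 fold changes were still -5.95, -5.03, -4.10, -4.57, -4.35 and -4.79.

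Fetal-like and regeneration genes rose as a group, with 16 of 18 higher and 0 lower, a median log2 fold change of 2.84 (adjusted p = 9.33e-10; adjusted p = 0.0134 with an estimated correlation). Anxa1, a phospholipid-binding protein made in injured epithelium, rose from 13.4 ± 0.695 to 189 ± 47.2 CPM. Il1rn, the interleukin-1 receptor antagonist, rose from 3.40 ± 1.11 to 43.2 ± 10.8 CPM, Anxa3 from 8.98 ± 0.0741 to 62.7 ± 17.9 CPM, and the urokinase receptor gene Plaur from 5.16 ± 0.168 to 37.9 ± 9.43 CPM. Crypt-base stem cell markers were mixed, with 6 of 12 higher and 1 lower, or 3 lower without adenoma 2 (adjusted p = 0.0228; adjusted p = 0.431 with an estimated correlation). Their median log2 fold change of 0.54 went to -0.01 under scaling by pan-epithelial genes. Lgr5, the R-spondin receptor that marks these cells, rose from 11.4 ± 1.06 to 55.2 ± 17.8 CPM, Igfbp4 from 51.0 ± 8.37 to 407 ± 56.1 CPM, Tnfrsf19 from 9.71 ± 2.30 to 83.7 ± 29.5 CPM and Ascl2 from 5.38 ± 0.428 to 14.6 ± 3.46 CPM. Lgr5, Tnfrsf19 and Ascl2 are also in the list of Wnt and beta-catenin targets, so their rise counts in both lists. Cdk6 was the lower member of the stem cell list, at a log2 fold change of -0.42 ± 0.16 (adjusted p = 0.0478). Leaving out any of 6 single libraries ended this call, with an adjusted p of up to 0.209. The list's own call was lost without wild type 1 (adjusted p = 0.101), without wild type 1 and adenoma 5 (0.112), with a filter of 5 CPM (0.0509) and with the sex pattern as a covariate (0.0506), where the median log2 fold change was 0.44.

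Enterocyte genes for digestion and absorption fell, with 17 of 26 lower and 0 higher, or 18 lower adjusted over the list alone, and a median log2 fold change of -2.76 (adjusted p = 1.71e-05; adjusted p = 0.470 with an estimated correlation). Slc15a1, the peptide transporter, fell from 810.0 ± 202 to 75.0 ± 33.2 CPM. Ace, angiotensin-converting enzyme, fell from 1674 ± 375 to 139.9 ± 91.1 CPM, the protease gene Mep1a from 118 ± 9.53 to 15.3 ± 8.97 CPM, and the peptidase gene Dpp4 from 845 ± 53.6 to 73.0 ± 42.1 CPM. Adenoma 2 had the lowest mean of this list, at -4.63 on the log2 scale from the other adenomas. Without it 24 members were lower and 1 higher, and without wild type 1 and adenoma 5 together 7 were lower. Genes of the proximal small intestine went both ways, 2 higher and 2 lower of 9 (adjusted p = 0.592), with a median log2 fold change of -0.67, or -0.36 without adenoma 2, but a mean of 0.01, and 4 were lower without adenoma 2. Lactase (Lct) fell from 2852 ± 1180.2 to 157 ± 207 CPM (adjusted p = 0.0335), and Slc40a1, which exports iron, rose from 18.2 ± 3.12 to 339.9 ± 353 CPM. The Lct call was lost when any wild-type library, adenoma 1 or adenoma 4 was left out, with an adjusted p of up to 0.0788. Genes of the distal small intestine had 5 of 7 lower and 2 higher (adjusted p = 0.133), and were called lower without adenoma 2 (adjusted p = 0.0246) and with a filter of 5 CPM (0.0179), with Slc51b falling from 41.3 ± 7.46 to 6.48 ± 3.61 CPM, Osr2 from 11.3 ± 1.60 to 1.07 ± 1.39 CPM, and the bile acid transporter gene Slc10a2 rising from 1.05 ± 0.695 to 3.17 ± 0.732 CPM.

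Secretory cell markers did not move as 1 block. Enteroendocrine markers fell, with 9 of 15 lower and 1 higher, or 10 lower adjusted over the list alone (adjusted p = 0.00423; adjusted p = 0.431 with an estimated correlation), and 13 were lower without adenoma 2. Neurotensin (Nts) fell from 22.8 ± 0.958 to 1.42 ± 1.51 CPM, somatostatin (Sst) from 9.75 ± 0.505 to 2.19 ± 0.802 CPM, and proglucagon (Gcg) from 19.8 ± 4.70 to 2.38 ± 1.54 CPM. Paneth cell markers had 6 of 13 lower and 2 higher (adjusted p = 0.125), and 3 lower without wild type 1 and adenoma 5, and were called lower without adenoma 3 (adjusted p = 0.0182). Defensin Defa24 fell from 2786 ± 290.2 to 509.9 ± 332 CPM, though near-identical defensin copies make its counts uncertain, and the secreted ribonuclease gene Ang4 from 195 ± 22.9 to 28.6 ± 13.7 CPM, while Habp2 rose from 14.4 ± 1.61 to 113 ± 56.3 CPM. Goblet cell markers had 7 of 14 higher and 4 lower (adjusted p = 0.176), with 1 lower without wild type 1 and adenoma 5, and were called higher without adenoma 2 (adjusted p = 0.0439). Spdef, a transcription factor of goblet cells, rose from 14.4 ± 0.598 to 53.7 ± 17.6 CPM and the resistin-like gene Retnlb from 0.124 ± 0.109 to 8.29 ± 4.19 CPM, whereas Muc2, the main gel-forming mucin, fell from 549 ± 176 to 259 ± 58.2 CPM. Tuft cell markers had 1 of 11 higher, or 2 without adenoma 2, and 3 lower (adjusted p = 0.579). Avil, an actin-binding protein, was the higher one, from 10.4 ± 2.57 to 221 ± 72.1 CPM, while the lipoxygenase gene Alox5 fell from 6.29 ± 0.428 to 2.95 ± 0.603 CPM.

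**Figure D3:**
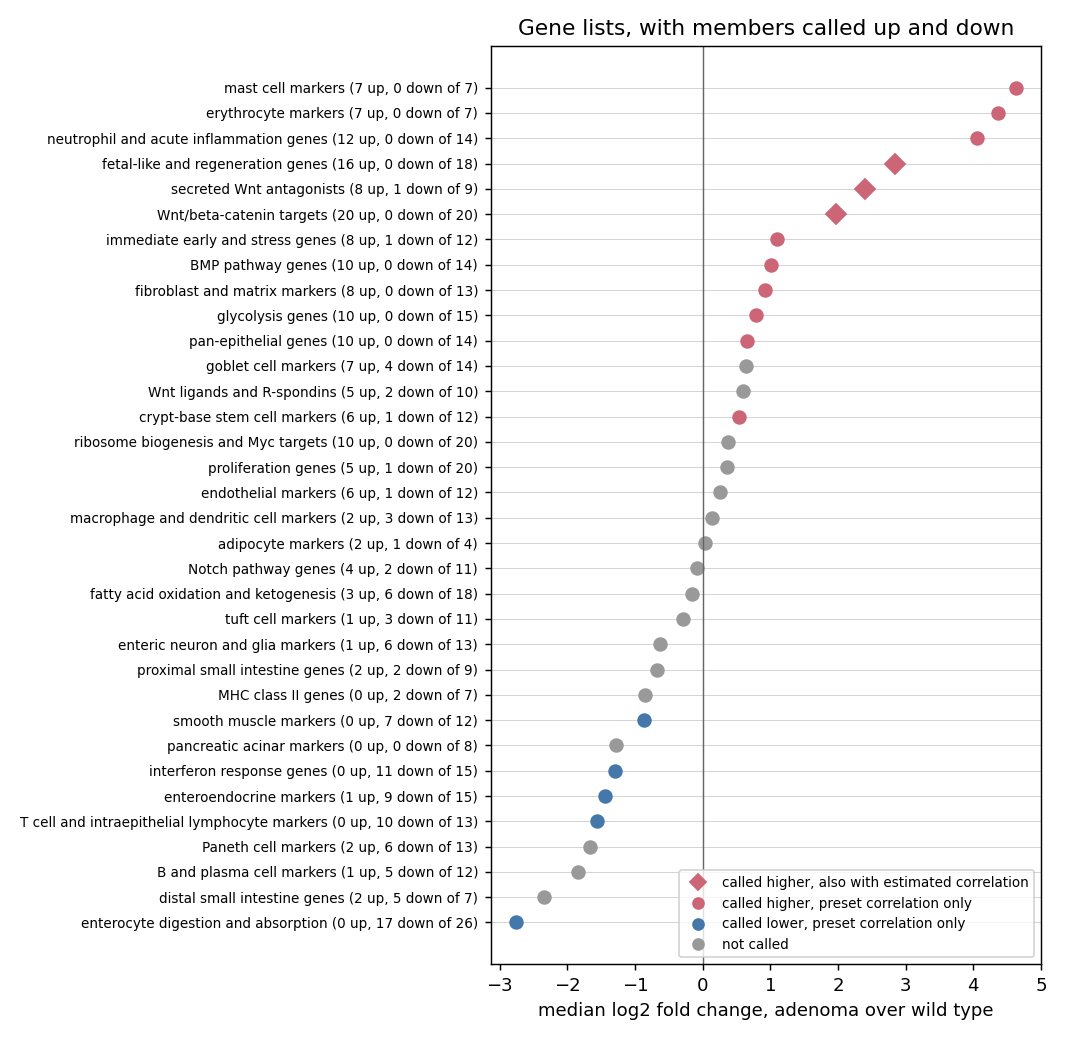
Median log2 fold change, adenoma over wild type, of the tested members of each of 34 gene lists (1 point per list, with its members called up and down in the label). Diamonds mark the 3 lists also called with an estimated correlation, from 1.97 to 2.84, and enterocyte genes have the lowest median at -2.76.

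Glycolysis genes rose, with 10 of 15 higher and 0 lower (adjusted p = 2.30e-04; adjusted p = 0.431 with an estimated correlation), and 13 were higher without adenoma 2. The glucose transporter gene Slc2a1 rose from 15.3 ± 3.21 to 104 ± 12.9 CPM, the hexokinase genes Hk1 from 23.1 ± 0.850 to 78.4 ± 11.6 CPM and Hk2 from 46.7 ± 12.003 to 149.6 ± 10.8 CPM, and Pfkl from 56.8 ± 5.39 to 287 ± 61.7 CPM. Fatty acid oxidation genes had 6 of 18 lower, or 5 adjusted over the list alone, and 3 higher (adjusted p = 0.244), with 5 higher and 6 lower without adenoma 2, and 3 each way without wild type 1 and adenoma 5. Ppargc1a, a coactivator of mitochondrial biogenesis, fell from 78.5 ± 3.90 to 10.2 ± 1.34 CPM, and Hadhb, a subunit of the mitochondrial trifunctional protein, from 34.7 ± 4.51 to 22.6 ± 2.54 CPM. Proliferation genes had 5 of 20 higher and 1 lower, with a median log2 fold change of 0.36 that turned to -0.24 under scaling by pan-epithelial genes (adjusted p = 0.142). Without adenoma 2, 13 of them were higher, and without wild type 1 and adenoma 5, 2 were, with a median of 0.19. The median was 0.20 without wild type 1, and the list was called higher without wild type 2 (adjusted p = 0.0303) and with no filter (0.0161). Pcna rose by 0.59 ± 0.13 and Mcm2 by 0.55 ± 0.14, the latter reversing in sign under scaling by pan-epithelial genes, while Mki67 fell by 0.61 ± 0.15 (log2 fold change -0.61), from 323 ± 60.5 to 211 ± 25.1 CPM. Ribosome biogenesis and Myc targets had 10 of 20 higher and 0 lower (adjusted p = 0.124), with a median log2 fold change of 0.37 that turned to -0.20 under the same scaling, and 6 were higher and 1 lower without wild type 1 and adenoma 5. This list was called higher without wild type 2 (adjusted p = 0.0249), without wild type 3 (0.0309) and with no filter (0.00869).

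BMP pathway genes rose, with 10 of 14 higher and 0 lower (adjusted p = 2.55e-04; adjusted p = 0.197 with an estimated correlation). Id3 and Id1, targets of BMP signalling, rose from 46.6 ± 2.57 to 147 ± 7.44 CPM and from 39.7 ± 3.15 to 125 ± 13.8 CPM, and the ligand gene Bmp7 from 10.9 ± 1.96 to 51.6 ± 5.34 CPM. Notch pathway genes had 4 of 11 higher and 2 lower (adjusted p = 0.176), with 5 lower without adenoma 2 and 1 lower without wild type 1 and adenoma 5. Their median log2 fold change of -0.08 and mean of 0.52 differed in sign, the test's direction being upward, and the median was 0.01 with library totals only, -0.20 without adenoma 2 and -0.55 under scaling by pan-epithelial genes. The Notch targets Hes1 and Hey1 rose from 22.3 ± 1.93 to 72.1 ± 7.28 CPM and from 2.22 ± 0.639 to 17.3 ± 5.36 CPM, and the ligand gene Dll1 fell from 56.5 ± 3.23 to 23.6 ± 7.73 CPM. Immediate early and stress genes had 8 of 12 higher and 1 lower (adjusted p = 0.0118; adjusted p = 0.444 with an estimated correlation). Ier3 rose from 6.08 ± 0.818 to 56.8 ± 15.3 CPM and Jun from 56.1 ± 10.8 to 164 ± 26.0 CPM, while Zfp36, which destabilises inflammatory transcripts, fell from 47.6 ± 5.56 to 18.1 ± 2.00 CPM. This call was lost with the sex pattern as a covariate (median log2 fold change 0.52 against 1.10, adjusted p = 0.0860) and with a filter of 5 CPM (1.00, adjusted p = 0.0509). Interferon response genes fell, with 11 of 15 lower and 0 higher and a median log2 fold change of -1.30 (adjusted p = 2.92e-05; adjusted p = 0.431 with an estimated correlation). Irf7 fell from 111 ± 27.5 to 29.6 ± 3.57 CPM, Oasl2 from 88.2 ± 38.4 to 11.4 ± 2.87 CPM and Ifit1 from 69.2 ± 24.3 to 9.15 ± 3.14 CPM.

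Among structural cell types, pan-epithelial genes had 10 of 14 higher, or 6 without wild type 1 and adenoma 5, and 0 lower (adjusted p = 0.0118; adjusted p = 0.431 with an estimated correlation), with the keratin gene Krt18 rising from 163 ± 28.6 to 950.2 ± 233 CPM and the splicing factor gene Esrp2 from 40.9 ± 1.96 to 87.6 ± 6.70 CPM. Fibroblast and matrix markers had 8 of 13 higher and 0 lower (adjusted p = 0.00247; adjusted p = 0.431 with an estimated correlation). Sparc rose from 97.2 ± 18.4 to 277 ± 13.5 CPM and the collagen gene Col1a2 from 218 ± 48.4 to 653 ± 109 CPM. Smooth muscle markers fell, with 7 of 12 lower and 0 higher (adjusted p = 0.0175; adjusted p = 0.543 with an estimated correlation), and 3 were lower without wild type 1 and adenoma 5. Smooth muscle myosin (Myh11) fell from 633 ± 186 to 201 ± 78.3 CPM and the kinase gene Mylk from 479 ± 94.9 to 198 ± 39.8 CPM. Scaling by pan-epithelial genes ended the smooth muscle call (adjusted p = 0.0668), with its median log2 fold change moving from -0.87 to -1.34, and the filter of 5 CPM ended the pan-epithelial one (adjusted p = 0.0564). The pan-epithelial call was also lost under scaling by these genes (adjusted p = 0.0549), which holds their summed counts equal by construction. Endothelial markers had 6 of 12 higher and 1 lower (adjusted p = 0.214), with a median log2 fold change of 0.26 that turned to -0.22 under scaling by pan-epithelial genes and was 0.43 without wild type 1. Vwf rose from 21.3 ± 4.14 to 83.9 ± 18.8 CPM and Flt4, a receptor of lymphatic vessels, fell from 16.4 ± 3.38 to 9.26 ± 0.937 CPM. Enteric neuron and glia markers had 6 of 13 lower and 1 higher (adjusted p = 0.176), among them the glial genes Gfap, from 1.20 ± 0.0793 to 0.299 ± 0.117 CPM, and Sox10, from 1.16 ± 0.159 to 0.351 ± 0.175 CPM. Adipocyte markers had 2 of 4 higher and 1 lower (adjusted p = 0.592), with Pparg rising from 9.45 ± 2.71 to 34.8 ± 6.83 CPM. The adipocyte median of 0.03 took either sign across the alternatives, from -0.61 with scaling by pan-epithelial genes to 0.21 without adenoma 2 and 0.23 with the sex pattern as a covariate.

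Immune genes split by cell type. T cell and intraepithelial lymphocyte markers fell, with 10 of 13 lower and 0 higher and a median log2 fold change of -1.56 (adjusted p = 1.29e-05; adjusted p = 0.286 with an estimated correlation). Cd160 fell from 9.03 ± 0.979 to 1.11 ± 0.0542 CPM, the integrin gene Itgae from 33.2 ± 2.26 to 11.8 ± 1.73 CPM, Cd8a from 16.4 ± 1.22 to 1.98 ± 0.925 CPM and Cd3e from 3.57 ± 0.670 to 0.384 ± 0.159 CPM. Neutrophil and acute inflammation genes rose, with 12 of 14 higher and 0 lower and a median log2 fold change of 4.06, which stayed 4.06 with its 1 member without wild-type counts at its bound (adjusted p = 1.15e-05; adjusted p = 0.368 with an estimated correlation). Ptgs2, which encodes cyclooxygenase 2, rose from 4.30 ± 0.452 to 43.2 ± 14.1 CPM, Il1b from 3.31 ± 0.470 to 23.6 ± 7.88 CPM and Il11 from 0.217 ± 0.102 to 15.9 ± 8.61 CPM. Mast cell markers had 7 of 7 higher (adjusted p = 0.0118; adjusted p = 0.431 with an estimated correlation), and 4 were higher without wild type 1 and adenoma 5. The protease gene Mcpt2 rose from 1.12 ± 0.603 to 34.3 ± 15.7 CPM and Tpsb2 from 0.126 ± 0.0333 to 4.07 ± 4.43 CPM. Erythrocyte markers had 7 of 7 higher with a median log2 fold change of 4.37 (adjusted p = 6.57e-05; adjusted p = 0.431 with an estimated correlation), among them haemoglobin Hbb-bs, from 6.65 ± 3.50 to 138 ± 59.3 CPM, whose reads can be shared with near-identical copies.

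The remaining immune lists were not called. B and plasma cell markers had 5 of 12 lower and 1 higher, or 4 lower and 0 higher adjusted over the list alone (adjusted p = 0.231), and 2 were lower without wild type 1 and adenoma 5. Without wild type 1 the call of Cr2 was lost, at adjusted p = 0.181. Macrophage and dendritic cell markers had 2 of 13 higher and 3 lower (adjusted p = 0.950). Their median log2 fold change of 0.13 and mean of 0.34 were above 0 while the test's direction was downward, and the median was -0.35 under scaling by pan-epithelial genes, -0.03 without adenoma 2, where 4 were lower, and -0.06 with the sex pattern as a covariate. Trem2 rose from 0.355 ± 0.0945 to 3.80 ± 2.86 CPM and Cd14 from 5.06 ± 0.688 to 35.0 ± 14.4 CPM, while the integrin gene Itgax fell from 40.4 ± 5.21 to 18.7 ± 2.12 CPM and Csf1r from 103 ± 2.65 to 58.2 ± 13.7 CPM. MHC class II genes had 2 of 7 lower and 0 higher (adjusted p = 0.125), and were called lower without wild type 3 (adjusted p = 0.0265) and under scaling by pan-epithelial genes (0.0119), with Ciita, their transactivator, falling from 49.1 ± 22.9 to 16.1 ± 5.84 CPM. Without adenoma 2, 5 were lower, and without wild type 1 and adenoma 5, 0 were. Pancreatic acinar markers had 0 of 8 called. Cela1, an elastase, was at 92.4 to 155 CPM in the adenomas, 3.57 and 3.55 CPM in wild type 2 and 3 and 114 CPM in wild type 1, so that its group difference (adjusted p = 0.270) passed the test without wild type 1 (adjusted p = 9.43e-05).

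Among the genes with the widest spread among adenomas, the pancreatic genes Cpa1 and Cela2a reached 89.2 and 95.7 CPM in adenoma 5 and at most 0.751 and 0.470 CPM in the other adenomas. Akp3, an alkaline phosphatase of the duodenum, ran from 1.69 CPM in adenoma 2 and 7.51 CPM in adenoma 3 to 594 CPM in adenoma 4 and 1808 CPM in adenoma 5. Prap1 was at 2.21 CPM in adenoma 2 and at 625 to 1509 CPM in the others, and Anxa10, an annexin of the stomach, at 0.235 CPM in adenoma 2 and 169 to 246 CPM in the others. Xist, Ddx3y and Eif2s3y, which separate adenoma 1 from the others, completed the set.

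**Figure D4:**
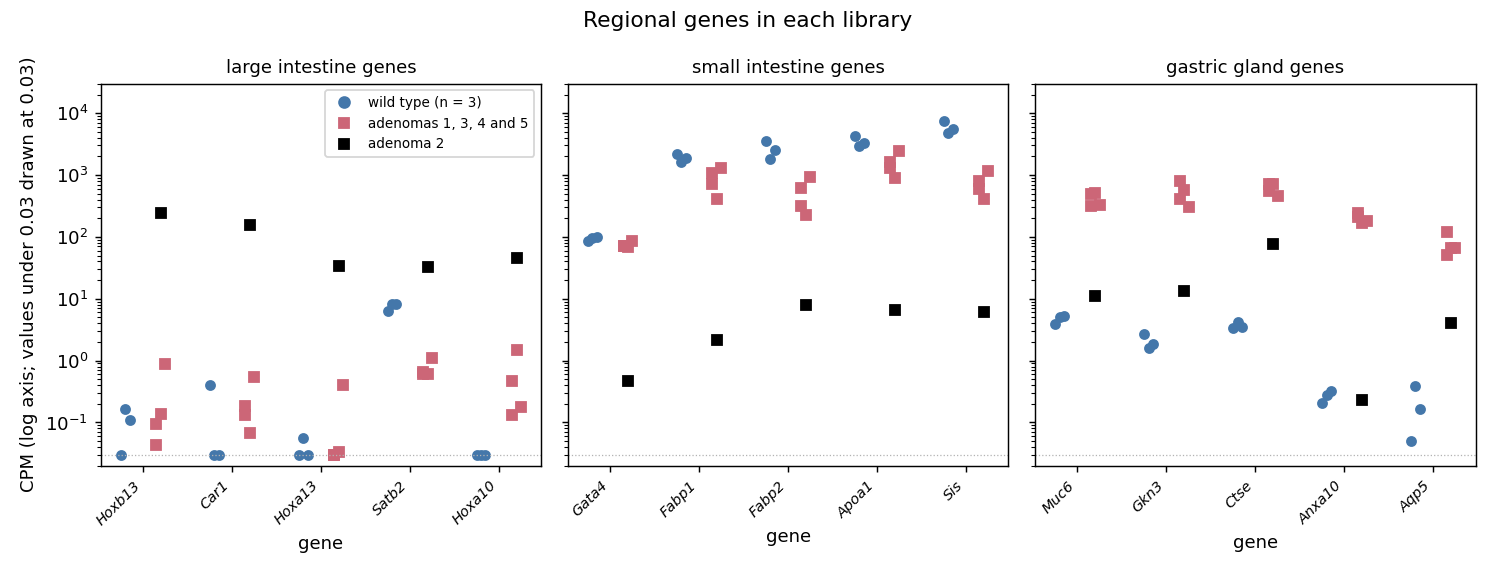
CPM per library on a log axis (values under 0.03 drawn at 0.03) of 15 genes of the large intestine, small intestine and gastric glands, chosen after the data were seen. Adenoma 2, in black, has the highest Hoxb13 at 245.5 CPM and the lowest Gata4 at 0.470 CPM, and its Muc6 at 11.3 CPM lies below the 318 to 510.1 CPM of the other adenomas.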

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

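In each of 202 results (161 genes, 34 list means, and measures of the libraries such as total counts and principal components), the 5 adenomas were tested for 1 library lying further from its neighbour than 0.71 of the whole range, which chance gives in about 1 in 20 groups. It was met by 27 results, 21 in adenoma 2, 3 in adenoma 1, 3 in adenoma 5 and 0 in adenomas 3 and 4. The genes include those taken for the largest SD over these same adenomas, for which that rate does not hold. Of the flagged genes, Anxa10, Prap1, Cela2a, Ddx3y, Eif2s3y and Xist were taken that way, the last 3 being all those of adenoma 1. Groups of 3 were not tested. The tests of sex, of a mixture and of low depth or poor RNA below were chosen after the result was seen, and that of large intestinal origin before its 13 genes were looked at.

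Adenoma 2 was the lowest adenoma for Anxa10 (0.235 CPM), Bpifb1 (0.329), Bpifb5 (2.77), Cd8a (0.517), Hadhb (18.2), Itln1 (73.2), Krt18 (552), Mki67 (166), Prap1 (2.21), Spdef (24.5), T (5.54) and Tcn2 (53.5). It was the highest for Cr2 (2.25 CPM), Klk1 (113), Krt36 (44.9) and Trem2 (8.87). It was also lowest in the list means, as log2 CPM less the mean of the other 4 adenomas, of enterocyte (-4.63), fatty acid oxidation (-0.75), MHC class II (-1.32) and proximal small intestine genes (-3.90), and at -103 on the second principal component. Adenoma 5 was the highest for Cela2a (95.7 CPM), Ctrb1 (191 CPM) and the mean of the pancreatic acinar list. That mean lay 7.23 above the mean of the other 4 adenomas in log2 CPM.

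The values of adenoma 2 are consistent with tissue of large intestinal origin. Of 13 further genes of the large intestine, 76.9%, or 10, were highest in adenoma 2, among them Hoxa10 at 46.3 CPM. Of these, 8 had at least 10 counts there, while Car4, Slc26a3 and Cyp2c55 were not highest in it. Hoxa10, Hoxa11, Hoxd10, Hoxd11 and Hoxd12 lie beside Hoxa13 or Hoxd13, which had been seen to be high in adenoma 2, so they were not independent of them. The others highest there were Aqp8, Fxyd4, Scnn1b, Scnn1g and Lypd8. A mixture of a small intestinal adenoma with large intestinal cells would have kept a share of small intestine transcripts, but the median of 12 such genes was 0.472% of the level in the other adenomas. Low depth or poor RNA would not raise such genes together. Of the same 13, 5 had at least 10 counts and stood more than 5 times as high as in any other library. Hoxa10, Hoxa11 and Hoxd11 among them were not independent, which leaves Fxyd4 and Scnn1b, too few to decide about poor RNA. Total counts of adenoma 2, at 19761919, were not the lowest, since wild type 3 had 18040301. The data do not show whether a lesion of the large intestine was taken or a label was exchanged, and the labels give no biological explanation that was tested.

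Adenoma 1 was the highest adenoma for the Y genes Ddx3y (75.6 CPM) and Eif2s3y (59.8 CPM) and the lowest for Xist (1.17 CPM), so it carried the male pattern of the 3 wild-type libraries and the other 4 adenomas the female one. A sex difference between the groups would leave adenoma 1 close to wild type. Genes were called with adenomas 2 to 5 against 2 wild-type libraries, and adenoma 1 was compared with the third, so that no control was shared and no change would give 50%. At the lowest of the 3 choices, 98.3% of 7733 genes moved the same way in adenoma 1, with a median log2 change of 1.08 there and 1.07 in adenomas 3, 4 and 5. This argues against sex as the whole cause of the group difference, while for a single gene a part played by sex stays open.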

How the results depend on the processing

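Over the 34 lists, 635 of 677 values under the alternatives kept their side of the threshold, 23 lost and 19 gained a call. Direction was compared only where a result was called in the main fit or the alternative. An uncalled result that changed direction therefore counts as kept. For the genes tested one by one, 3686 of 4004 values were kept by the same rule, 272 lost a call, 36 gained one and 10 reversed. Where calls moved, the cause was not tested unless fewer libraries or genes were used. Genes higher numbered 1343 with scaling by pan-epithelial genes, where 60.4% of the 10657 genes called were called again and 1477 had the opposite sign, 3345 with a replicate block and 3074 with the sex pattern as a covariate. Genes lower numbered 3204 with the block and 2298 with the covariate. Genes changed by more than a factor of 2 numbered 1316 with a filter of 5 CPM, 1217 with the block, 1561 with limma-voom, 1401 without wild type 1 and adenoma 5 and 855 with the covariate. The replicate numbers did not pair libraries, the correlations of shared numbers being -0.02, 0.05 and 0.06 against 0.14 for the highest of the other pairs. Lists higher numbered 3 and lists lower 0 with an estimated inter-gene correlation, and fry called 16 higher and 8 lower. Fry added 7 calls to those of the preset test. Wnt ligands and R-spondins, goblet, Notch and endothelial genes were added as higher. Paneth, distal small intestine and enteric neuron and glia genes were added as lower. Leaving out 1 library at a time gave 4529 to 6184 genes higher, 4135 to 6092 lower and 1705 to 3200 changed by more than a factor of 2.

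Apc was at -0.44 (adjusted p = 0.0703) with the block and -0.41 with the covariate. With scaling by pan-epithelial genes Mcm7 turned to -0.0824, Mcm2 to -0.0252, Pes1 to -0.19, Nop58 to -0.00760, Rrp9 to -0.0375, Nop56 to -0.0460, Tie1 to -0.0219 and Mzb1 to -0.0835. Xist turned to -0.48 with the covariate, which removes it by construction. Fxyd4 ranged from -1.33 without adenoma 2 to 1.13 without adenoma 4. At these depths, group sizes and dispersions, 40% of simulated changes by a factor of 2 were recovered where few genes were changed, none of them with low counts. This share does not give what the real fit recovers, and depth was not varied by itself.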

Other observations

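Genes of gastric mucous glands were high in adenomas 1, 3, 4 and 5. These and the other genes of this part, and the tests of where they come from, were chosen after the result was seen. Muc6, the mucin of gland cells, was at 318 to 510.1 CPM in these adenomas, 11.3 CPM in adenoma 2 and 3.87 to 5.35 CPM in wild type, a log2 fold change of 6.13 ± 1.20 (adjusted p = 0.00348). Gkn3 was at 303 to 798 CPM in the same 4 adenomas (log2 fold change 7.67 ± 1.37), Ctse at 460 to 721 CPM (7.09 ± 0.84) and Aqp5 at 51.6 to 119.5 CPM. Vsig1 rose by 8.12 ± 0.62 (adjusted p = 3.47e-05). Adenoma 2 lay below those 4 adenomas but above every wild-type library for Ctse, at 76.5 against at most 4.18 CPM. The same held for Gkn3 (13.1 against at most 2.70 CPM), Vsig1 (9.63 against at most 0.102 CPM) and Aqp5 (3.99 against at most 0.390 CPM). Its Anxa10, at 0.235 CPM, and Tff2, at 0.376 CPM, lay within the wild-type range, and Cldn18 had 4 counts in it. All 8 of the gastric mucous and gland genes were called higher, though the call of Tff2 was lost without any 1 of the wild-type libraries, adenoma 4 and adenoma 5, with an adjusted p of up to 0.111. Of 12 genes of gastric surface, chief, parietal and endocrine cells, 9 were tested and 8 were higher, among them Gkn1, Tff1 and Pgc. Hdc, also among the 8, was highest in adenoma 2, at 10.1 CPM, the adenoma where Gkn1, Tff1 and Pgc were lowest. Without wild type 2 or without wild type 3 the calls of Gkn2, Muc5ac and Hdc were lost, with an adjusted p of up to 0.0948, 0.0532 and 0.112. The calls of Gkn2 and Hdc were also lost without wild type 1, adenoma 1 or adenoma 4, and that of Gkn2 without adenoma 3.

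Of 5 genes of the upper duodenum, 4 were called higher, and Slc30a10 did not pass (adjusted p = 0.474). Akp3 was at 594 and 1808 CPM in adenomas 4 and 5 and at most 38.9 CPM in the other adenomas, Cybrd1, the duodenal iron reductase, at 517 and 1252 CPM against at most 45.8 CPM, and Pdx1 at 18.2 and 38.4 CPM against at most 3.36 CPM. The difference between adenomas was not tested. The calls of Akp3 and Cybrd1 were lost without any 1 of the wild-type libraries, adenoma 4 and adenoma 5, and that of Pdx1 without any wild-type library, with adjusted p of up to 0.125, 0.0988 and 0.0831.

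Stomach tissue carried into the samples would bring the other cells of the stomach. The median of 12 genes of surface, chief, parietal and endocrine cells was 1.16% of the mean of Muc6 and Gkn3, which was 468.7 CPM. The single genes ran from 0 for Gast and Chia1 to 4.65% for Tff1, 5.93% for Atp4a and 12.5% for Gkn1. No stomach library gives the share these genes have there, so the low median does not exclude carried stomach tissue. Submucosal gland tissue from the upper duodenum cannot be told apart from expression by adenoma cells, since the ratio to Muc6 varied by a factor of 17.7 for Tff2 but 1.71 for Gkn3, 1.26 for Ctse and 2.01 for Anxa10, and the labels do not give the site of each adenoma.

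All 56 splits of the 8 libraries into groups of 3 and 5 were refitted. For the counts of genes, 1 split, the real one, gave 5558 higher, 5099 lower and 2417 changed by more than a factor of 2. Any other split gave 0 by edgeR, where up to 4864 genes had an unadjusted p below 0.05. Each other split mixes the groups, so the group difference enters the spread within them, and their 0 calls cannot exclude chance. Chance cannot be excluded for the counts of lists with the preset correlation. The 12 lists higher were matched in 3 of the 56 splits, with at most 13 in another, and the 5 lower in 42, with at most 14 in another. The other splits that matched the lists higher set 2 wild-type libraries and adenoma 1 against the rest. They kept part of the group difference, so they do not show how many lists chance alone calls. Each of the 55 other splits called at least 1 list, with a median of 13. With an estimated correlation or fry, 0 lists were called in any other split, all of which mix the groups. The real split gave the smallest preset p of all splits for Wnt and beta-catenin targets, secreted Wnt antagonists and fetal-like genes.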
